A study of Homo sapiens with 18 samples.

How the data were processed

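Bulk RNA sequencing was analysed for 18 libraries of SK-N-AS, an established human neuroblastoma cell line. Per the labels' protocols, the cells carried Cas9 and a guide, were selected with puromycin, and from 9 days after infection received DMSO, the solvent, or trametinib at 3 nM, an inhibitor of the kinase MEK (MEKi below), for 4 days, after which RNA was purified with a column kit. The labels give each library 1 guide: sgLacZ, which names a bacterial gene used as a control target, sgCCNC or sgCDK8. The design text instead speaks of a vector with both sgCCNC and sgCDK8, and the library labels were followed. The 3 guides and both treatments make 6 groups of 3 libraries. Nothing says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The labels mark sgCCNC MEKi replicate 1 as removed for low quality, and it was left out of every comparison, which leaves 17 libraries and 2 in that group.

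The deposited count table holds whole read counts per gene, not normalized, for 18 libraries, with GENCODE v30 gene identifiers per the file headers. It has 58870 lines, of which 1 names no gene, holds 0 counts and was removed. Per the submitters' processing notes, FastQC 0.11.9, MultiQC 1.7, STAR 2.6.1d, featureCounts 1.6.3, Subread 2.0.0, DESeq2 1.32.0 and the build hg38 were used, with no role or order given. The strand setting, the handling of reads that fit several genes and the read filters are not given in the sources used here. Values of genes with near-identical copies, such as MAGEA2, and of overlapping or antisense genes are therefore uncertain. The second deposited table holds log2 values of TPM plus 1 by the authors for 17 libraries, without the one marked as removed, and how TPM were estimated is not given in the sources used here. Gene positions and types came from GENCODE 29 on GRCh38, the assembly that hg38 names, where 58596 gene identifiers matched without their version suffix.

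Total counts ran from 9337649 to 14347025 per library. Replicates differed by more than sampling noise in each group, so none was treated as a repeat of another. At these depths a gene at 1 CPM (counts scaled to a common library total) rests on about 10 reads per library, and folds of such genes carry wide errors. Where a group held 0 counts over its libraries, the fold was set against a floor of 3 counts over the group and is written as at least that size. With 1 to 3 counts the ratio is given with its exact 95% counting interval. Such intervals and floors cover counting error only. The share of counts on mitochondrial genes and on small RNA (snRNA, snoRNA, scaRNA, rRNA, mitochondrial rRNA and miscellaneous RNA) was computed per library as a sign of RNA quality.

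Tests used R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by edgeR's filterByExpr over the 6 groups (16459 genes), libraries were scaled by TMM, and 1 model with a coefficient per group was fitted with the robust quasi-likelihood F test, so that the groups share 1 estimate of the spread. Adjusted p is Benjamini-Hochberg over the genes tested, and a gene is called higher or lower, or said to rise or fall, at adjusted p under 0.05. Levels are TMM-scaled CPM with their SD. There were 11 comparisons: MEKi against DMSO within each guide, each guide against sgLacZ under each treatment, both guides against each other under each treatment, and 2 interactions, which test whether the change with MEKi differs between sgCCNC or sgCDK8 and sgLacZ.

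Before the data were examined, 25 gene lists of 497 genes (497 matched, 462 tested), the groups, tests, alternatives and the rule for named genes were fixed. The lists cover MEK-ERK pathway output, immediate early genes, the Mediator kinase module, Mediator core, DNA replication and S phase, mitosis, mesenchymal and adrenergic neuroblastoma identity, neuronal differentiation, interferon-stimulated genes, antigen presentation, TGF-beta and SMAD targets, Wnt and beta-catenin targets, Notch targets, sterol and fatty acid synthesis, p53 targets, receptor tyrosine kinases, the integrated stress response, MYC targets and ribosome biogenesis, hypoxia and glycolysis, extracellular matrix, the BCL2 family, and markers of Schwann and glial, epithelial and blood cells. Each list was tested against the other genes with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01 and adjustment over the lists of a comparison. An adjusted p with an estimated correlation stands beside it where that ends the call, and fry was run as well. Members are counted after adjustment over all genes tested and adjusted over the list alone. The rule for named genes takes the Mediator kinase module and, per comparison, the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM. Libraries of the groups compared must not overlap, except in the interactions, and clone, LOC, LINC, antisense, numbered pseudogene and mitochondrial names are passed over. It adds up to 4 members per direction of each list by smallest adjusted p and every member of the MEK-ERK list. Some genes that the rule took are not reported here. The genes printed were picked from those the rule took after their values were seen.

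The size of the MEKi response was compared between guides by an orthogonal slope through the origin over genes called for MEKi in the guide on neither axis. Overlap of the guides' changes is given beside 20 simulations of unchanged groups against the same control libraries and beside the overlap of independent lists. The computations were tested on simulated data with known answers. For MEKi against DMSO in sgLacZ, over 15909 genes, 68.7%, 82.1% and 92.4% of genes changed by 1.5, 2 and 4-fold were recovered, and 6.36% of the calls were false. For MEKi against DMSO in sgCCNC with its 2 libraries, over 15933 genes, these were 71.6%, 74.6% and 97.0%, with 6.90% false. For the sgCDK8 interaction, over 15931 genes, they were 56.7%, 82.1% and 90.9%, with 3.77% false. A slope of 0.8 was recovered as 0.801, and camera called a list raised by 1.5-fold and not an unchanged one. Genes varied independently in that simulation, so it does not test camera's preset correlation. In each simulated comparison only 67, 67 and 66 genes were changed, by 1.5, 2 and 4-fold, and 173, 174 and 159 genes were called. The real data gave 6662 calls for MEKi in sgLacZ, 6904 in sgCCNC and 568 for the sgCDK8 interaction. The scaling and the rates of recovered genes and false calls were thus not tested where so many genes change.

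Each result was recomputed with RLE factors, with DESeq2 1.42.0, with no filter on low counts, with a filter of 10 reads in 3 libraries, with the replicate number as a block, with only the groups compared in the fit, with the removed library kept in, with limma on the deposited log2 TPM, and without each library in turn. Lists were recomputed with an estimated correlation, RLE factors and the block, the slopes over genes with an absolute log2 fold change of at least 1, and the overlap at adjusted p under 0.01.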

Results

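RNA was sequenced from SK-N-AS neuroblastoma cells carrying Cas9 and a guide labelled sgLacZ, sgCCNC or sgCDK8 and given DMSO or the MEK inhibitor trametinib (MEKi) at 3 nM for 4 days. The series title asks about CDK8 inhibition as a partner of MEK inhibitors. CDK8 is a kinase of the Mediator complex and cyclin C, the product of CCNC, is its activating partner. Each of the 6 groups holds 3 libraries except sgCCNC under MEKi, which holds 2 after 1 library marked as removed was left out. Libraries held 9337649 to 14347025 counts, and 16459 genes were tested. Each fold is followed by the log2 fold change ± its SE, and genes said to rise or fall passed edgeR's test. For a list, its median log2 fold change and the adjusted p of camera are given.

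The targeted genes were looked at first, since they check the labels. CCNC (ENSG00000112237.13, chromosome 6, 99542380 to 99568973, minus strand, GRCh38) stood at 79.1, 77.2 and 71.1 CPM in the sgLacZ DMSO libraries and at 75.5, 75.6 and 84.7 CPM under MEKi. In libraries labelled sgCCNC it stood at 66.6, 71.5 and 66.5 CPM in DMSO and at 77.2 and 65.6 CPM under MEKi. In libraries labelled sgCDK8 it stood at 29.9, 30.9 and 27.9 CPM in DMSO and at 38.9, 49.1 and 44.2 CPM under MEKi. CDK8 (ENSG00000132964.12, chromosome 13, 26254104 to 26405238, plus strand) stood at 36.0, 33.4 and 37.7 CPM in sgLacZ DMSO and at 28.9, 30.4 and 29.8 CPM under MEKi. In libraries labelled sgCCNC it stood at 34.5, 36.2 and 36.9 CPM in DMSO and at 27.1 and 24.9 CPM under MEKi. In libraries labelled sgCDK8 it stood at 41.2, 35.4 and 36.9 CPM in DMSO and at 34.4, 33.3 and 39.1 CPM under MEKi.

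Against sgLacZ in DMSO, CCNC mRNA fell 2.57-fold (log2 -1.36 ± 0.08) in libraries labelled sgCDK8, adjusted p = 9.06e-16, and each of the 3 lay below each sgLacZ library. CDK8 mRNA did not pass there (log2 0.08 ± 0.08, adjusted p = 0.492). In libraries labelled sgCCNC, CCNC did not pass the test in DMSO (log2 -0.15 ± 0.07, adjusted p = 0.102), although with only the groups compared in the fit it did (log2 -0.17, adjusted p = 0.0244), and neither did CDK8 (log2 0.00 ± 0.08, adjusted p = 0.992). Under MEKi, CCNC fell 1.78-fold (log2 -0.83 ± 0.08) in libraries labelled sgCDK8, while CDK8 was higher by log2 0.25 ± 0.09 (adjusted p = 0.0193, and 0.20 with limma on the deposited log2 TPM). That call on CDK8 also ended without sgLacZ MEKi replicate 1 (adjusted p = 0.0558) or sgCDK8 MEKi replicate 3 (adjusted p = 0.108). In libraries labelled sgCCNC under MEKi, CCNC (log2 -0.14 ± 0.08, adjusted p = 0.158) and CDK8 (log2 -0.19 ± 0.10, adjusted p = 0.0954) did not pass. CDK19, the paralog of CDK8 (ENSG00000155111.15, chromosome 6, 110609978 to 110815958, minus strand), passed in none of the comparisons between guides, with log2 -0.14 ± 0.10 here. The mRNA of the gene that the guide names thus did not pass as lower under either label, and CCNC mRNA was lower under the sgCDK8 label. Where the guides bind is not given in the sources used here, Cas9 edits DNA, and an edited gene need not lose mRNA. Directions below are therefore those of libraries by label.

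**Figure D1:**
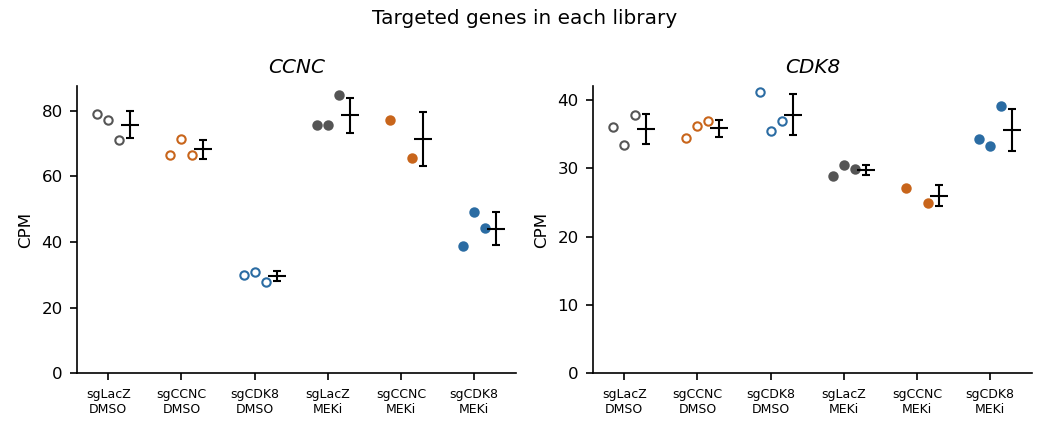
CCNC and CDK8 in each of the 17 libraries compared, in TMM-scaled CPM (vertical axis) by group (horizontal axis). Open circles stand for DMSO, filled circles for MEKi, and bars for the mean ± SD. CCNC lies between 27.9 and 49.1 CPM in the libraries labelled sgCDK8 and between 65.6 and 84.7 CPM in the others shown. The library marked as removed, sgCCNC MEKi replicate 1, is not shown and held CCNC at 29.4 CPM of its total counts.

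MEKi against DMSO in the control guide asked what the drug does alone (n = 3 and 3). VGF, a secreted neuropeptide precursor induced by growth factors, fell 120.3-fold (log2 -6.91 ± 0.09), from 1220.5 ± 75.6 CPM (SD, n = 3) to 10.2 ± 1.21 CPM (SD, n = 3). The ERK phosphatase DUSP6 fell 8.86-fold (log2 -3.15 ± 0.12), the transcription factor ETV4 fell 8.65-fold (log2 -3.11 ± 0.09) and the feedback inhibitor SPRY4 fell 6.68-fold (log2 -2.74 ± 0.12). IL1B, a cytokine, was lower by a ratio of 302 (95% counting interval 83.2 to 2498), and the transporter gene ABCA10 was lower at least 31.8-fold. TM4SF4, a tetraspanin-like membrane protein, rose 94.2-fold (log2 6.56 ± 0.23). In the MEK-ERK list, 9 of 10 tested members fell and 1 rose (9 and 1 adjusted over the list alone, median -2.26, adjusted p = 1.40e-12). Its riser was the receptor EPHA4 (log2 0.65 ± 0.21, adjusted p = 0.0111), a call that ended with limma on log2 TPM (0.0774) and without sgLacZ DMSO replicate 2 (0.0860) or 3 (0.0580) or sgLacZ MEKi replicate 3 (0.132). Among immediate early genes, 21 of 30 tested members fell and 0 rose (21 and 0 adjusted over the list alone, median -1.04, adjusted p = 2.65e-12), led by the transcription factors EGR2, which fell 26.4-fold (log2 -4.72 ± 0.23), and FOSL1, which fell 11.8-fold (log2 -3.55 ± 0.13).

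Of the mesenchymal neuroblastoma list, 13 of 23 tested members fell and 4 rose (15 and 4 adjusted over the list alone, median -0.58, adjusted p = 2.77e-06). The hyaluronan receptor CD44 fell 14.9-fold (log2 -3.90 ± 0.06), from 335 ± 10.4 CPM (SD, n = 3) to 22.4 ± 1.14 CPM (SD, n = 3), and the homeobox factor PRRX1 fell 5.55-fold (log2 -2.47 ± 0.07). Adrenergic genes went both ways: DBH, which makes noradrenaline, rose 9.92-fold (log2 3.31 ± 0.23), whereas DDC, which makes dopamine, fell 5.88-fold (log2 -2.55 ± 0.11). That list was not called, as 9 rose and 7 fell of 17 (9 and 7 adjusted over the list alone, median 0.14, adjusted p = 0.572). Of extracellular matrix genes, 17 of 27 tested members fell and 5 rose (18 and 5 adjusted over the list alone, median -0.60, adjusted p = 1.28e-08). THBS2, a matrix glycoprotein, fell 14.5-fold (log2 -3.86 ± 0.08) and the fibrillar collagen gene COL5A1 rose 1.67-fold (log2 0.74 ± 0.05). For antigen presentation, 12 of 14 tested members fell and 0 rose (12 and 0 adjusted over the list alone, median -0.68, adjusted p = 1.00e-08). The class I light chain gene B2M fell 2.38-fold (log2 -1.25 ± 0.04). For interferon-stimulated genes, 20 of 28 tested members fell and 1 rose (21 and 1 adjusted over the list alone, median -0.94, adjusted p = 1.41e-06, and adjusted p = 0.0945 with an estimated correlation). IFI35 fell 2.81-fold (log2 -1.49 ± 0.12).

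Genes of DNA replication rose: 25 of 30 tested members rose and 0 fell (26 and 1 adjusted over the list alone, median 0.33, adjusted p = 1.07e-10). For MYC targets, 17 of 24 tested members rose and 1 fell (17 and 2 adjusted over the list alone, median 0.26, adjusted p = 3.09e-05). ODC1, of polyamine synthesis, rose 1.51-fold (log2 0.60 ± 0.05). For TGF-beta targets, 9 of 18 tested members fell and 0 rose (9 and 0 adjusted over the list alone, median -0.34, adjusted p = 9.42e-05, and adjusted p = 0.0541 with an estimated correlation). For sterol and fatty acid synthesis, 13 of 27 tested members fell and 3 rose (13 and 4 adjusted over the list alone, median -0.10, adjusted p = 0.0104, and adjusted p = 0.20 with an estimated correlation). Receptor tyrosine kinases were called lower, 10 of 27 tested members fell and 8 rose (10 and 8 adjusted over the list alone, median -0.07, adjusted p = 0.0446, and adjusted p = 0.20 with an estimated correlation). For epithelial markers, 4 of 5 tested members fell and 0 rose (4 and 0 adjusted over the list alone, median -1.06, adjusted p = 0.00104).

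The remaining lists were not called. For mitosis, 5 rose and 4 fell of 30 (5 and 4 adjusted over the list alone, median 0.02, adjusted p = 0.508). For the Mediator kinase module, 4 rose and 1 fell of 7 (4 and 1 adjusted over the list alone, median 0.16, adjusted p = 0.246). Mediator core gave 8 rose and 3 fell of 26 (8 and 3 adjusted over the list alone, median 0.08, adjusted p = 0.18). Neuronal differentiation gave 8 rose and 10 fell of 24 (8 and 10 adjusted over the list alone, median 0.02, adjusted p = 0.374), where the mean and the test were negative, while of granule proteins CHGA rose 7.57-fold (log2 2.92 ± 0.13) and SCG2 fell 8.66-fold (log2 -3.11 ± 0.05). For Wnt targets, 2 rose and 3 fell of 12 (2 and 3 adjusted over the list alone, median 0.20, adjusted p = 0.636), with a negative mean and test too. Notch targets gave 4 rose and 0 fell of 7 (4 and 0 adjusted over the list alone, median 0.44, adjusted p = 0.18) and p53 targets 11 rose and 4 fell of 20 (11 and 4 adjusted over the list alone, median 0.30, adjusted p = 0.228). For the integrated stress response, 12 rose and 5 fell of 23 (13 and 7 adjusted over the list alone, median 0.18, adjusted p = 0.108). For hypoxia and glycolysis, 5 rose and 12 fell of 23 (6 and 12 adjusted over the list alone, median -0.14, adjusted p = 0.149). For the BCL2 family, 4 rose and 5 fell of 14 (4 and 7 adjusted over the list alone, median -0.03, adjusted p = 0.835). Schwann and glial markers gave 1 rose and 2 fell of 6 (1 and 2 adjusted over the list alone, median -0.26, adjusted p = 0.508) and blood cell markers 1 rose and 2 fell of 5 (1 and 2 adjusted over the list alone, median -0.05, adjusted p = 0.177).

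In edgeR's test 6662 genes were called, 3239 higher and 3423 lower, of which 304 and 1030 by at least 2-fold. Camera called 12 of 25 lists, 8 of them also with an estimated correlation. Beside these gene groups, the mitochondrial share of counts was 2.95% to 3.11% in DMSO and 3.48% to 3.9% under MEKi, and that of small RNA 0.498% to 0.523% and 0.577% to 0.721%.

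The same drug contrast in libraries labelled sgCCNC (n = 2 and 3) gave a fall of DUSP6 by 7.27-fold (log2 -2.86 ± 0.12), of ETV4 by 8.31-fold (log2 -3.06 ± 0.10) and of FOSL1 by 8.95-fold (log2 -3.16 ± 0.12). PADI3, a protein-modifying enzyme, was lower at least 69.5-fold, and FGFBP2, a secreted protein, was higher by a ratio of 256 (95% counting interval 87.1 to 1244). TM4SF4 rose 89.9-fold (log2 6.49 ± 0.20) and TNNT2, a troponin of heart muscle, rose 30.6-fold (log2 4.93 ± 0.38). PHGDH, the first enzyme of serine synthesis, rose 3.27-fold (log2 1.71 ± 0.07), and the matrix protein SPARC rose 1.47-fold (log2 0.56 ± 0.05) to 2138 ± 4.86 CPM (SD, n = 2). Most other matrix genes were lower, 17 of 27 tested members fell and 9 rose (17 and 9 adjusted over the list alone, median -0.56, adjusted p = 0.00118, and adjusted p = 0.259 with an estimated correlation). Epithelial markers were lower too, 4 of 5 tested members fell and 0 rose (4 and 0 adjusted over the list alone, median -0.81, adjusted p = 0.00908, and adjusted p = 0.066 with an estimated correlation). Of MEK-ERK output genes, 9 of 10 tested members fell and 0 rose (9 and 0 adjusted over the list alone, median -1.82, adjusted p = 2.35e-12). Among immediate early genes, 22 of 30 tested members fell and 3 rose (22 and 3 adjusted over the list alone, median -1.29, adjusted p = 4.18e-13). Mitosis genes were lower, 13 of 30 tested members fell and 2 rose (13 and 2 adjusted over the list alone, median -0.12, adjusted p = 0.00507, and adjusted p = 0.275 with an estimated correlation). The kinetochore motor CENPE fell 3.11-fold (log2 -1.64 ± 0.10). For adrenergic genes, 11 of 17 tested members rose and 5 fell (11 and 5 adjusted over the list alone, median 0.50, adjusted p = 0.0316, and adjusted p = 0.117 with an estimated correlation). For sterol synthesis, 18 of 27 tested members fell and 0 rose (19 and 0 adjusted over the list alone, median -0.22, adjusted p = 3.88e-06, and adjusted p = 0.066 with an estimated correlation).

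By edgeR 6904 genes were called, 3410 higher and 3494 lower, and 49.4% of the calls were higher. The share was 33.0% with limma on log2 TPM, but 54.7% with RLE factors, 53.8% with DESeq2 and 51.1% without sgCCNC MEKi replicate 2, so its majority direction was not settled. Camera called 11 lists, 2 of which held with an estimated correlation, and the other 14 had adjusted p from 0.275 to 0.913. The mitochondrial share was 2.86% to 3.2% in DMSO and 3.57% to 4.47% under MEKi, and the small RNA share 0.433% to 0.526% and 0.759% to 0.932%.

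In libraries labelled sgCDK8 (n = 3 and 3), VGF fell 55.5-fold (log2 -5.79 ± 0.08), DUSP6 9.12-fold (log2 -3.19 ± 0.11) and FOSL1 13.5-fold (log2 -3.75 ± 0.12) with MEKi. KRT16, a keratin, was lower at least 45.1-fold, and MYL7, a myosin light chain of atrial muscle, was higher by a ratio of 91.3 (95% counting interval 24.9 to 759.5). CD44 fell 8.89-fold (log2 -3.15 ± 0.05). CCNC itself rose 1.5-fold (log2 0.58 ± 0.08) with the drug. Among MEK-ERK output genes, 9 of 10 tested members fell and 0 rose (9 and 0 adjusted over the list alone, median -1.93, adjusted p = 2.10e-12). Genes of DNA replication rose, 19 of 30 tested members rose and 1 fell (19 and 1 adjusted over the list alone, median 0.22, adjusted p = 2.35e-06). Of the markers of other cell types, epithelial ones fell, 4 of 5 tested members fell and 0 rose (4 and 0 adjusted over the list alone, median -0.89, adjusted p = 0.00369), and blood cell ones were called lower, 2 of 5 tested members fell and 0 rose (2 and 0 adjusted over the list alone, median -0.72, adjusted p = 0.0417, and adjusted p = 0.0873 with an estimated correlation). For antigen presentation, 11 of 14 tested members fell and 1 rose (11 and 2 adjusted over the list alone, median -0.54, adjusted p = 1.10e-05). B2M fell 1.89-fold (log2 -0.92 ± 0.04). For sterol synthesis, 18 of 27 tested members fell and 1 rose (19 and 1 adjusted over the list alone, median -0.28, adjusted p = 1.13e-06). The desaturase FADS2 fell 1.9-fold (log2 -0.93 ± 0.05).

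Here edgeR called 6955 genes, 3371 higher and 3584 lower, and camera called 11 lists, of which 9 held with an estimated correlation. The mitochondrial share was 2.88% to 3.49% in DMSO and 3.82% to 4.9% under MEKi, and the small RNA share 0.52% to 0.575% and 0.729% to 1.21%. The size of the drug response was set against that in sgLacZ by a slope over genes picked in the remaining guide. It was 0.977 for libraries labelled sgCDK8 (6904 genes, across-gene r = 0.884, leave-one-out range 0.945 to 1.02) and 1.07 for those labelled sgCCNC (6955 genes, r = 0.825, range 1.03 to 1.16). For genes higher with MEKi the slopes were 1.2 and 1.55, in the same order, and for lower genes 0.922 and 0.952. Genes are not independent replicates, and these slopes carry no test. Both labels also share changes from sgLacZ, so picking genes in 1 of them is not neutral. Slopes split by direction may be shifted by it.

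Libraries labelled sgCCNC were compared with sgLacZ in DMSO (n = 3 and 3), and CCNC mRNA had not passed as lower in them. PHGDH fell 8.37-fold (log2 -3.06 ± 0.06), from 211 ± 7.0 CPM (SD, n = 3) to 25.2 ± 0.724 CPM (SD, n = 3), and the stress regulator ATF4 fell 1.97-fold (log2 -0.98 ± 0.05). For the integrated stress response, 12 of 23 tested members fell and 4 rose (12 and 4 adjusted over the list alone, median -0.37, adjusted p = 3.86e-05). The Notch-responsive repressor HES4 fell 6.7-fold (log2 -2.74 ± 0.12) and HEY1 fell 3.09-fold (log2 -1.63 ± 0.07). Among Notch targets 6 of 7 tested members fell and 0 rose (6 and 0 adjusted over the list alone, median -1.94, adjusted p = 3.86e-05). Matrix genes rose, 18 of 27 tested members rose and 5 fell (18 and 5 adjusted over the list alone, median 0.54, adjusted p = 1.28e-06, and adjusted p = 0.0534 with an estimated correlation). SPARC rose 2.07-fold (log2 1.05 ± 0.04) and the proteoglycan LUM rose 1.85-fold (log2 0.89 ± 0.04), though the fibrillin gene FBN2 fell 5.62-fold (log2 -2.49 ± 0.16). DUSP6 rose 1.68-fold (log2 0.75 ± 0.09) and CCND1, which drives G1 progression, rose 1.8-fold (log2 0.85 ± 0.05). In the MEK-ERK list 9 of 10 tested members rose and 1 fell (9 and 1 adjusted over the list alone, median 0.52, adjusted p = 3.67e-05). Adrenergic factors rose, 12 of 17 tested members rose and 2 fell (13 and 2 adjusted over the list alone, median 0.44, adjusted p = 3.86e-05). GATA3 rose 1.83-fold (log2 0.87 ± 0.06) and TBX2 rose 1.95-fold (log2 0.96 ± 0.05). For sterol synthesis, 18 of 27 tested members rose and 1 fell (18 and 1 adjusted over the list alone, median 0.34, adjusted p = 2.41e-06).

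Immediate early genes were called higher, 20 of 30 tested members rose and 2 fell (22 and 2 adjusted over the list alone, median 0.49, adjusted p = 2.41e-06, and adjusted p = 0.0534 with an estimated correlation). FOSL1 rose 2.16-fold (log2 1.11 ± 0.08) while JUN fell 2.54-fold (log2 -1.35 ± 0.22). DNA replication genes fell, 18 of 30 tested members fell and 0 rose (18 and 0 adjusted over the list alone, median -0.23, adjusted p = 2.42e-05, and adjusted p = 0.0534 with an estimated correlation). The licensing factor CDT1 fell 2.83-fold (log2 -1.50 ± 0.08). For mitosis, 19 of 30 tested members fell and 1 rose (20 and 1 adjusted over the list alone, median -0.20, adjusted p = 0.000708, and adjusted p = 0.158 with an estimated correlation). The kinase AURKB fell 2.2-fold (log2 -1.14 ± 0.08). MAGEA2, a cancer-testis gene with a near-identical copy and therefore an uncertain value, fell 30.1-fold (log2 -4.91 ± 0.49). By edgeR 7182 genes were called, 3473 higher and 3709 lower, of which 240 and 1260 by at least 2-fold. Camera called 13 lists and 5 held with an estimated correlation.

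Libraries labelled sgCDK8, in which CCNC mRNA was lower and CDK8 mRNA was not, were compared with sgLacZ in DMSO next (n = 3 and 3). Sterol and fatty acid genes rose, 22 of 27 tested members rose and 1 fell (23 and 1 adjusted over the list alone, median 0.26, adjusted p = 9.22e-11). FADS2 rose 1.53-fold (log2 0.62 ± 0.04) and MSMO1, of cholesterol synthesis, rose 1.53-fold (log2 0.61 ± 0.06). HES4 fell 2.17-fold (log2 -1.12 ± 0.10) and PHGDH fell 1.89-fold (log2 -0.92 ± 0.05). Among Notch targets 4 of 7 tested members fell and 0 rose (5 and 1 adjusted over the list alone, median -0.76, adjusted p = 0.0263, and adjusted p = 0.0928 with an estimated correlation). For the stress response, 11 of 23 tested members fell and 2 rose (12 and 2 adjusted over the list alone, median -0.22, adjusted p = 0.00272, and adjusted p = 0.0606 with an estimated correlation). The imprinted RNA H19 fell 6.46-fold (log2 -2.69 ± 0.10) and IL1B fell 6.77-fold (log2 -2.76 ± 0.23). DUSP6 rose 1.64-fold (log2 0.72 ± 0.09) and ETV5 rose 1.47-fold (log2 0.56 ± 0.07). Of MEK-ERK output genes, 7 of 10 tested members rose and 1 fell (7 and 1 adjusted over the list alone, median 0.29, adjusted p = 0.00875, and adjusted p = 0.143 with an estimated correlation). SPARC rose 1.5-fold (log2 0.59 ± 0.04) and LUM rose 1.71-fold (log2 0.77 ± 0.04). For matrix genes, 13 of 27 tested members rose and 4 fell (13 and 6 adjusted over the list alone, median 0.11, adjusted p = 0.00081, and adjusted p = 0.246 with an estimated correlation). For mitosis, 21 of 30 tested members fell and 0 rose (22 and 0 adjusted over the list alone, median -0.20, adjusted p = 2.50e-09, and adjusted p = 0.0606 with an estimated correlation). CENPE fell 2.07-fold (log2 -1.05 ± 0.09). For DNA replication, 16 of 30 tested members fell and 0 rose (17 and 0 adjusted over the list alone, median -0.16, adjusted p = 4.43e-05, and adjusted p = 0.0928 with an estimated correlation).

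Here edgeR called 5566 genes, 2823 higher and 2743 lower, while limma on log2 TPM called 3139. The share of higher calls was 50.7% and, with limma on log2 TPM, 39.2%. Camera called 9 lists, and 1 held with an estimated correlation.

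Both guide labels were set against the same sgLacZ libraries, so their changes share chance values. In DMSO 2066 genes were higher and 1762 lower under both labels, and 137 went opposite ways. Independent lists of these sizes would share 596 and 618. The 20 simulations of unchanged groups shared 0, but groups without any effect have almost no calls. That 0 was thus fixed in advance and does not show what unrelated effects would share through the controls. The covariance of the fold changes was 0.270 against 0.0532 simulated, a difference of 0.217. Their across-gene correlation was 0.587 against 0.509 simulated on average and 0.563 at most, a smaller excess. Under MEKi 2566 genes were higher and 2180 lower under both labels and 71 opposite, against 799.5 and 771 for independent lists. The covariance was 0.393 against 0.0586 simulated, a difference of 0.334. The correlation was 0.693 against 0.475 simulated on average and 0.533 at most. The simulated covariances and correlations already carry the shared controls, at the spread fitted between libraries. A difference particular to the sgLacZ libraries beyond that spread would still add to both. The overlap of independent lists leaves the shared controls out, and the 3 control libraries were not split. Part of the excess over independent lists may thus come from the shared controls.

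Under MEKi, libraries labelled sgCCNC (n = 2) were compared with sgLacZ (n = 3). The matrix genes SPARC and LUM rose 4.87-fold (log2 2.28 ± 0.05) and 4.14-fold (log2 2.05 ± 0.05), and COL3A1, a fibrillar collagen, rose 2.41-fold (log2 1.27 ± 0.04), whereas the basement membrane collagen COL4A2 fell 2.52-fold (log2 -1.33 ± 0.09). For extracellular matrix, 19 of 27 tested members rose and 6 fell (19 and 6 adjusted over the list alone, median 0.82, adjusted p = 1.61e-07). For interferon-stimulated genes, 24 of 28 tested members rose and 1 fell (25 and 1 adjusted over the list alone, median 1.12, adjusted p = 2.85e-07, and adjusted p = 0.0699 with an estimated correlation). IFI35 rose 2.72-fold (log2 1.44 ± 0.13). B2M rose 2.28-fold (log2 1.19 ± 0.05) while HLA-C fell 1.76-fold (log2 -0.81 ± 0.05). For antigen presentation, 9 of 14 tested members rose and 4 fell (9 and 4 adjusted over the list alone, median 0.63, adjusted p = 0.014, and adjusted p = 0.198 with an estimated correlation). Among adrenergic genes, 14 of 17 tested members rose and 1 fell (14 and 1 adjusted over the list alone, median 0.72, adjusted p = 7.71e-07). Mesenchymal identity genes were called higher as well, as 16 of 23 tested members rose and 5 fell (16 and 5 adjusted over the list alone, median 0.75, adjusted p = 0.000724, and adjusted p = 0.063 with an estimated correlation). Among MEK-ERK output genes, 8 of 10 tested members rose and 1 fell (9 and 1 adjusted over the list alone, median 0.84, adjusted p = 8.91e-05). The phosphatase DUSP4 rose 2.74-fold (log2 1.45 ± 0.09) and DUSP6 rose 2.05-fold (log2 1.04 ± 0.14).

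Lower groups included DNA replication, where 26 of 30 tested members fell and 0 rose (26 and 0 adjusted over the list alone, median -0.56, adjusted p = 1.29e-10). For mitosis, 23 of 30 tested members fell and 0 rose (23 and 0 adjusted over the list alone, median -0.39, adjusted p = 1.61e-07). CENPE fell 2.8-fold (log2 -1.48 ± 0.10). Notch targets were lower, 6 of 7 tested members fell and 0 rose (6 and 0 adjusted over the list alone, median -1.55, adjusted p = 0.000543). HEY1 fell 3.91-fold (log2 -1.97 ± 0.08). Stress response genes were lower too, 16 of 23 tested members fell and 1 rose (17 and 2 adjusted over the list alone, median -0.57, adjusted p = 7.71e-07). PHGDH fell 3.88-fold (log2 -1.96 ± 0.06). GREM1, which binds bone morphogenetic proteins, rose 10.1-fold (log2 3.34 ± 0.14). In all, edgeR called 9110 genes, 4404 higher and 4706 lower, and 14 lists were called, 8 of them with an estimated correlation too. Higher genes were 48.3% of the calls, but 52.2% with RLE factors, 52.0% with DESeq2, 54.4% without sgLacZ MEKi replicate 1, 51.4% without sgCCNC MEKi replicate 2 and 38.6% with limma on log2 TPM, so the majority direction was not settled here either. Small RNA made up 0.759% to 0.932% of counts here and 0.577% to 0.721% in sgLacZ under MEKi.

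Under MEKi, libraries labelled sgCDK8 (n = 3 and 3) were compared with sgLacZ. ACTA2, smooth muscle actin, rose 7.31-fold (log2 2.87 ± 0.17), from 16.3 ± 5.26 CPM (SD, n = 3) to 119 ± 13.8 CPM (SD, n = 3), the actin-binding TAGLN rose 8.02-fold (log2 3.00 ± 0.18), and CNN1, a calponin, was higher by a ratio of 72.8 (95% counting interval 19.8 to 606). For matrix genes, 19 of 27 tested members rose and 3 fell (20 and 3 adjusted over the list alone, median 0.50, adjusted p = 1.55e-12). SPARC rose 2.89-fold (log2 1.53 ± 0.05) and LUM rose 3.09-fold (log2 1.63 ± 0.05). For interferon-stimulated genes, 22 of 28 tested members rose and 0 fell (23 and 0 adjusted over the list alone, median 0.74, adjusted p = 1.96e-09, and adjusted p = 0.0681 with an estimated correlation). ISG15, a ubiquitin-like modifier, rose 2.72-fold (log2 1.44 ± 0.16). For antigen presentation, 8 of 14 tested members rose and 0 fell (8 and 2 adjusted over the list alone, median 0.43, adjusted p = 0.00124, and adjusted p = 0.0915 with an estimated correlation). B2M rose 1.49-fold (log2 0.57 ± 0.04). In the MEK-ERK list, 8 of 10 tested members rose and 1 fell (9 and 1 adjusted over the list alone, median 0.45, adjusted p = 5.08e-05). The receptor EPHA2 rose 1.65-fold (log2 0.72 ± 0.07). DUSP6 rose 1.59-fold (log2 0.67 ± 0.14) (adjusted p = 0.00175), a call that limma on log2 TPM ended (adjusted p = 0.0770).

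Mitosis genes fell, 25 of 30 tested members fell and 0 rose (28 and 0 adjusted over the list alone, median -0.24, adjusted p = 6.82e-12). CENPE fell 2.6-fold (log2 -1.38 ± 0.09). For DNA replication, 21 of 30 tested members fell and 0 rose (24 and 0 adjusted over the list alone, median -0.22, adjusted p = 2.14e-09). The polymerase POLE fell 1.51-fold (log2 -0.59 ± 0.06). For p53 targets, 12 of 20 tested members fell and 2 rose (12 and 2 adjusted over the list alone, median -0.37, adjusted p = 0.00163, and adjusted p = 0.0915 with an estimated correlation). AEN, a nuclease, fell 1.75-fold (log2 -0.81 ± 0.07). The imprinted RNA MEG3 fell 7.31-fold (log2 -2.87 ± 0.17). By edgeR 5683 genes were called, 2988 higher and 2695 lower, against 3382 with limma on log2 TPM, where 34.3% rather than 52.6% of calls were higher. Camera called 11 lists, 4 also with an estimated correlation. Small RNA made up 0.729% to 1.21% of counts here and 0.577% to 0.721% in sgLacZ under MEKi.

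**Figure D2:**
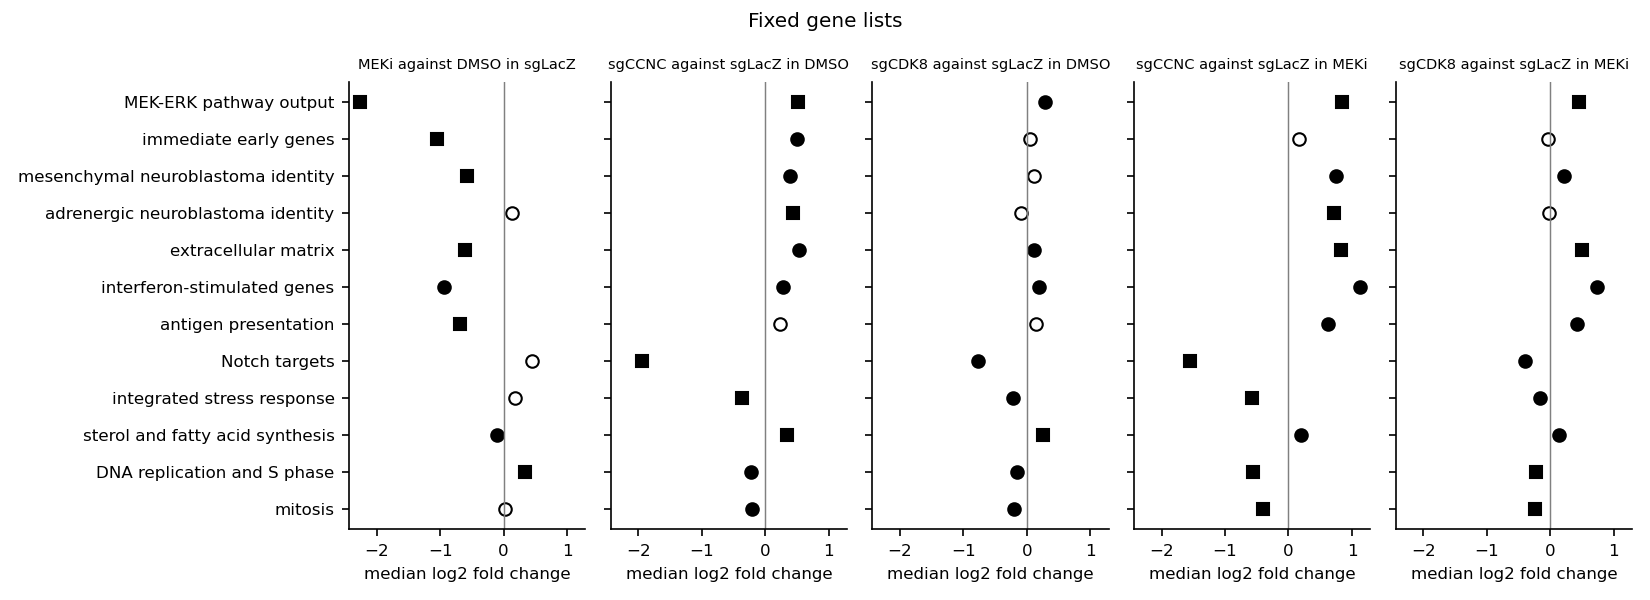
Median log2 fold change (horizontal axis) of 12 gene lists in 5 comparisons, filled where camera called the list, square where the call also held with an estimated correlation, and open where the list was not called. MEK-ERK output has a median of -2.26 with MEKi in sgLacZ and of 0.84 and 0.45 in libraries labelled sgCCNC and sgCDK8 against sgLacZ under MEKi.

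Set against each other in DMSO (n = 3 and 3), libraries labelled sgCDK8 held more PHGDH mRNA than those labelled sgCCNC by 4.43-fold (log2 2.15 ± 0.06) and more HES4 by 3.08-fold (log2 1.62 ± 0.13). For the stress response, 12 of 23 tested members were higher and 2 lower (12 and 2 adjusted over the list alone, median 0.25, adjusted p = 1.06e-05). Among Notch targets, 5 of 7 tested members were higher and 0 lower (7 and 0 adjusted over the list alone, median 1.12, adjusted p = 1.06e-05). Adrenergic genes were lower, 13 of 17 tested members were lower and 0 higher (13 and 0 adjusted over the list alone, median -0.46, adjusted p = 1.04e-09). PHOX2A was lower by 1.84-fold (log2 -0.88 ± 0.06) and HAND2 by 1.38-fold (log2 -0.46 ± 0.04). Camera called the mesenchymal identity list there as well (adjusted p = 0.0117, and adjusted p = 0.161 with an estimated correlation). CCND1 was lower by 1.47-fold (log2 -0.56 ± 0.05). Of MEK-ERK output genes 5 of 10 tested members were lower and 0 higher (5 and 0 adjusted over the list alone, median -0.15, adjusted p = 0.00367, and adjusted p = 0.0864 with an estimated correlation). CCNC was lower by 2.31-fold (log2 -1.21 ± 0.08). By edgeR 4954 genes were called, 2816 higher and 2138 lower, against 2817 with limma on log2 TPM, where 46.1% rather than 56.8% were higher.

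Under MEKi (n = 3 and 2) GREM1 was lower in libraries labelled sgCDK8 by 5.21-fold (log2 -2.38 ± 0.13). For adrenergic genes, 16 of 17 tested members were lower and 0 higher (16 and 0 adjusted over the list alone, median -0.61, adjusted p = 6.19e-13). Camera called the mesenchymal identity list too (adjusted p = 0.00261, and adjusted p = 0.105 with an estimated correlation). PHGDH was higher by 2.87-fold (log2 1.52 ± 0.06). For the stress response, 15 of 23 tested members were higher and 0 lower (15 and 0 adjusted over the list alone, median 0.32, adjusted p = 3.06e-09). For DNA replication, 22 of 30 tested members were higher and 2 lower (22 and 3 adjusted over the list alone, median 0.35, adjusted p = 4.74e-09). CDT1 was higher by 2.05-fold (log2 1.03 ± 0.08). For MYC targets, 16 of 24 tested members were higher and 1 lower (16 and 2 adjusted over the list alone, median 0.26, adjusted p = 7.40e-06). The nucleolar protein NPM1 was higher by 1.47-fold (log2 0.56 ± 0.04). Among Notch targets, 5 of 7 tested members were higher and 0 lower (6 and 0 adjusted over the list alone, median 1.06, adjusted p = 0.000314). HEY1 was higher by 2.96-fold (log2 1.57 ± 0.08). By edgeR 5775 genes were called, 3088 higher and 2687 lower, against 3467 with limma on log2 TPM. The share of higher calls was 53.5%, but 45.7% with RLE factors, 46.6% with DESeq2, and 43.5%, 43.9% and 42.9% without sgCDK8 MEKi replicate 1, 2 and 3, so which direction held more calls was not settled.

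The interactions asked whether the change with MEKi differed from that in sgLacZ. Between libraries labelled sgCCNC and sgLacZ, the change of B2M was higher by log2 0.90 ± 0.06 (adjusted p = 1.57e-13), that of SPARC by log2 1.24 ± 0.07 and that of CD44 by log2 1.11 ± 0.08. The change of the proliferation marker MKI67 was lower by log2 -1.96 ± 0.25 and that of CENPE by log2 -1.62 ± 0.13. The mitosis list as a whole differed less, with a median of -0.157 (adjusted p = 1.17e-05, and adjusted p = 0.106 with an estimated correlation). The change of DUSP6 passed no threshold (log2 0.28 ± 0.17, adjusted p = 0.283), but it did with no filter (log2 0.31, adjusted p = 0.0125) and with only the groups compared (adjusted p = 0.0323), and DUSP4 differed by log2 0.67 ± 0.11. For matrix genes, 14 of 27 tested members had a higher change and 5 a lower one (15 and 5 adjusted over the list alone, median 0.41, adjusted p = 2.06e-06, and adjusted p = 0.106 with an estimated correlation). For interferon-stimulated genes, 15 of 28 tested members had a higher change and 0 a lower one (15 and 0 adjusted over the list alone, median 0.68, adjusted p = 8.80e-07, and adjusted p = 0.106 with an estimated correlation). For DNA replication, 15 of 30 tested members had a lower change and 0 a higher one (16 and 0 adjusted over the list alone, median -0.28, adjusted p = 2.57e-08, and adjusted p = 0.0791 with an estimated correlation). By edgeR 3613 genes were called, 2020 higher and 1593 lower, against 1604 with limma on log2 TPM, where 39.2% rather than 55.9% were higher, and 1767 with the removed library kept in. Of the 11 lists called, 0 held with an estimated correlation.

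Between libraries labelled sgCDK8 and sgLacZ, the change of SPARC with MEKi was higher by log2 0.95 ± 0.06 (adjusted p = 2.09e-11), that of LUM by log2 0.85 ± 0.06 and that of COL3A1 by log2 0.66 ± 0.05. The change of ISG15 was higher by log2 1.36 ± 0.22, that of B2M by log2 0.33 ± 0.06 and that of PRRX1 by log2 0.67 ± 0.10. ARC, an activity-regulated gene of neurons, differed by log2 -1.15 ± 0.15, while DUSP6 did not pass (log2 -0.04 ± 0.17, adjusted p = 0.951). For matrix genes, 13 of 27 tested members had a higher change and 1 a lower one (15 and 1 adjusted over the list alone, median 0.30, adjusted p = 1.20e-16), which held with an estimated correlation. For interferon-stimulated genes, 7 of 28 tested members had a higher change and 0 a lower one (12 and 0 adjusted over the list alone, median 0.46, adjusted p = 2.74e-09, and adjusted p = 0.0844 with an estimated correlation). For antigen presentation, 2 of 14 tested members had a higher change and 0 a lower one (6 and 0 adjusted over the list alone, median 0.21, adjusted p = 3.21e-05, and adjusted p = 0.0844 with an estimated correlation). By edgeR 568 genes were called, 406 higher and 162 lower. Only 107 were called with limma on log2 TPM, where 82.2% rather than 71.5% were higher, 49 with the removed library kept in and 375 without sgCDK8 DMSO replicate 2.

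With the library marked as removed kept in, the calls of 47 of 280 gene results picked from those the naming rule took ended, and EGR3 in the sgCCNC interaction turned its sign without passing. Where sgCCNC MEKi was compared the changes themselves shrank, for DUSP6 with MEKi in sgCCNC from log2 -2.86 to -1.31, and elsewhere they hardly moved, for DUSP6 with sgCDK8 in DMSO from 0.72 to 0.71. For DUSP6 they ended with MEKi in sgCCNC (adjusted p = 0.0931) and against sgLacZ for sgCCNC in DMSO (0.304), sgCDK8 in DMSO (0.382) and sgCDK8 under MEKi (0.485). Calls above that ended too were PADI3, ETV4 and SPARC with MEKi in sgCCNC, CCNC with MEKi in sgCDK8, FOSL1 for sgCCNC in DMSO, SPARC and ETV5 for sgCDK8 in DMSO, and EPHA2 and CDK8 for sgCDK8 under MEKi. Of the interactions, SPARC was lost in both and PRRX1, COL3A1 and ARC in sgCDK8.

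Across the 11 comparisons the median, mean and test of a list differed in sign only among lists not called, in 1 to 7 lists per comparison.

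**Figure D3:**
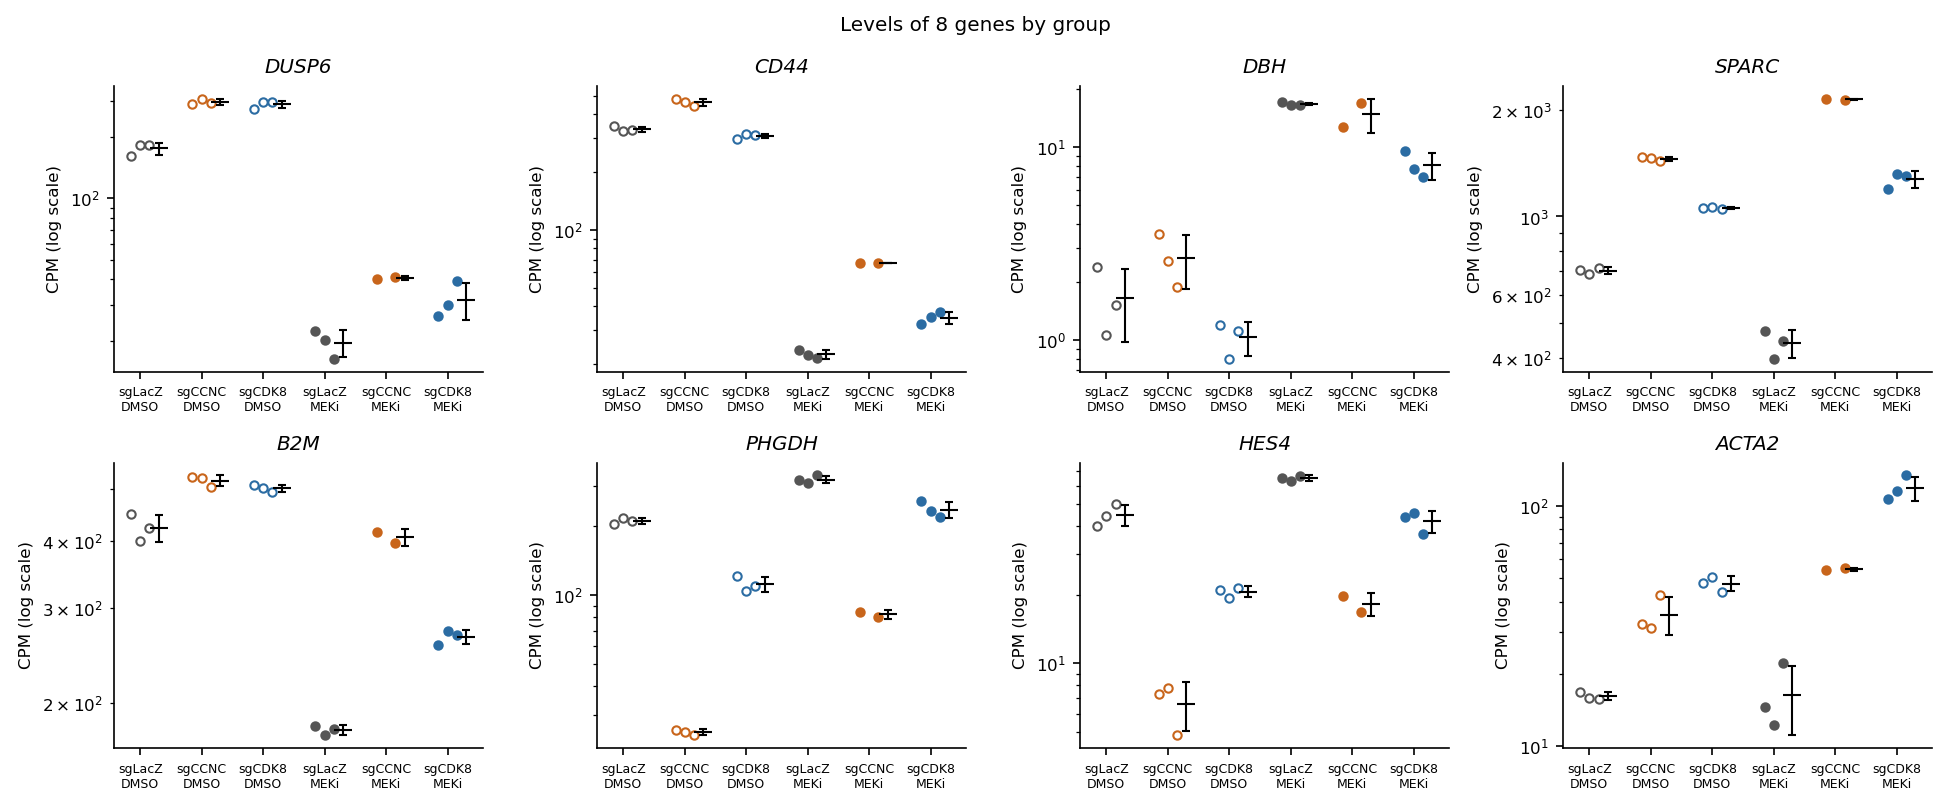
CPM on a log scale (vertical axis) of 8 genes in each of the 17 libraries compared, by group (horizontal axis). Open circles stand for DMSO, filled ones for MEKi, and bars for the mean ± SD. SPARC lies higher in both guide labels than in sgLacZ under each treatment, and CD44 lies lower under MEKi under each label.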

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

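The tests of the library marked as removed, of CCNC and of the contractile genes below, with their gene and marker lists, were chosen after those results were seen, while the counts of other splits were planned.

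The interactions tested directly whether the change with MEKi differed between a guide and sgLacZ, and the differences that passed in edgeR's test are given here as log2. In libraries labelled sgCCNC 3613 genes differed. The change was higher for IFITM1 by 3.77, MAGEA2 by 3.63, RSPO2 by 3.36, ISG15 by 1.52, SPARC by 1.24, LUM by 1.16, CD44 by 1.11, B2M by 0.90, DUSP4 by 0.67 and SPRY2 by 0.61. It differed by -3.15 for EGR3, -2.84 for COL7A1, -1.96 for MKI67, -1.62 for CENPE, -1.03 for COL4A1 and -0.41 for MCM4. The call ended for MCM4 with limma on log2 TPM (adjusted p = 0.0778) and for SPRY2 without sgCCNC MEKi replicate 3 (adjusted p = 0.0712). With the removed library kept in it ended for RSPO2 (0.422), COL7A1 (0.572), COL4A1 (0.0558) and SPARC (0.0514), and EGR3 turned its sign without passing. Among lists called there, medians were 0.68 for interferon-stimulated genes, 0.41 for extracellular matrix, 0.39 for antigen presentation, 0.32 for adrenergic and 0.15 for mesenchymal identity. They were -0.28 for DNA replication, -0.19 for the Mediator kinase module, -0.16 for mitosis, -0.11 for immediate early genes, -0.11 for sterol synthesis and -0.0873 for MYC targets. With an estimated correlation none of these 11 lists held, with adjusted p = 0.0791 for DNA replication, adrenergic identity and antigen presentation as the smallest and adjusted p = 0.314 for immediate early genes as the largest, and RLE factors ended the calls of the kinase module and sterol lists (both adjusted p = 0.0522).

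In libraries labelled sgCDK8 568 genes differed. The change was higher for IFI44L by 2.92, IFITM1 by 2.82, LMOD1 by 2.63, CEMIP by 2.10, ISG15 by 1.36, SPARC by 0.95, LUM by 0.85, CD44 by 0.75, PRRX1 by 0.67, COL3A1 by 0.66, CCNC by 0.53, EPHA2 by 0.42, B2M by 0.33 and PHLDA1 by 0.31. It differed by -1.36 for NPY2R, -1.28 for CSPG4, -1.15 for ARC and -0.32 for LSS. Limma on log2 TPM ended the calls of CEMIP (adjusted p = 0.985), EPHA2 (0.364), LSS (0.325), IFI44L (0.279), PHLDA1 (0.251), CD44 (0.191), CSPG4 (0.164), CCNC (0.123), NPY2R (0.0940) and LMOD1 (0.0759). With limma the difference of CEMIP shrank to log2 0.03, that of LMOD1 to 1.19 and that of IFI44L to 1.72. For CD44 (0.72) and LSS (-0.35) it kept about its size. The call of IFITM1 ended without sgCDK8 MEKi replicate 2 (adjusted p = 0.0708) and that of IFI44L without sgLacZ MEKi replicate 2 (adjusted p = 0.0554). Of the genes named, LMOD1, ISG15, LUM and B2M were still called with the removed library kept in, and the others were not. List medians were 0.46 for interferon-stimulated genes, 0.30 for extracellular matrix, 0.21 for antigen presentation, 0.15 for mesenchymal identity and 0.10 for MEK-ERK output. They were -0.14 for sterol synthesis, -0.14 for p53 targets, -0.0813 for DNA replication, -0.0749 for immediate early genes and -0.0411 for mitosis. With an estimated correlation the extracellular matrix list held (adjusted p = 0.0271) and the other 9 did not, from adjusted p = 0.0520 for sterol synthesis and adjusted p = 0.0844 for interferon-stimulated genes and antigen presentation to adjusted p = 0.407 for mitosis.

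The library marked as removed, sgCCNC MEKi replicate 1, entered no comparison and held DUSP6 at 280 CPM of its total counts. Means of DUSP6 were 40.3 CPM in the other sgCCNC MEKi libraries and 177, 291 and 284 CPM in sgLacZ, sgCCNC and sgCDK8 DMSO. DUSP6 alone thus does not single out sgCDK8 DMSO. Low depth would need a small total, but this library held 9.69 M counts and the smallest other library 9.34 M. A mixture of sgCCNC MEKi and sgCDK8 DMSO cultures would need levels in between, but the library's median share of the sgCCNC MEKi excess was -0.0073 (quartiles -0.0151 and 0.00426). Mixtures with other groups were not tested. The share was taken over 35 genes at least 8-fold higher in the other sgCCNC MEKi libraries than in sgCDK8 DMSO. A single wrong label is a candidate explanation: its median position from the other sgCCNC MEKi libraries (0) to sgCDK8 DMSO (1) was 0.969 over 1488 genes (quartiles 0.783 and 1.09), and it lay 0.403 from the sgCDK8 DMSO mean, where libraries left out of their own groups lay 0.378 to 0.449 away. Its CCNC level was 29.4 CPM, against 29.1 CPM in sgCDK8 DMSO. It had the fewest genes with at least 5 counts, 15892, where sgCDK8 MEKi replicate 3 had 15944. Its mitochondrial share was 3.73%, above sgCDK8 DMSO (2.88% to 3.49%) and within the other sgCCNC MEKi libraries (3.57% to 4.47%). Its small RNA share was 0.552%, within sgCDK8 DMSO (0.52% to 0.575%) and below the other sgCCNC MEKi libraries (0.759% to 0.932%). Low quality other than depth is thus not excluded, and how the library came by its label stays open.

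CCNC mRNA was low in libraries labelled sgCDK8 and not in the compared libraries labelled sgCCNC. The library marked as removed, also labelled sgCCNC, held it at 29.4 CPM of its total counts. Scaling of the libraries was argued against, since the smallest fall of CCNC over the other scalings was -1.35 on the log2 scale in DMSO. If the guide labels had been exchanged and each guide lowered its own mRNA, CDK8 would be low in libraries labelled sgCCNC, where its log2 fold change in DMSO was 0.00149. Under MEKi CDK8 did not pass as lower there against sgLacZ. It was higher by log2 0.45 in libraries labelled sgCDK8 than in those labelled sgCCNC under MEKi, the direction that an exchange would give. That call passed by edgeR (adjusted p = 0.000294) and ended with the removed library kept in (adjusted p = 0.268). Since an edited gene need not lose mRNA, exchanged labels cannot be told apart from guides acting as labelled by these values. An effect of the guide named in the label, by which CCNC mRNA may fall when CDK8 is targeted, stays open and untested.

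Contractile genes (ACTA2, TAGLN, CNN1, TPM1, TPM2, CALD1, MYLK, LMOD1, SMTN and ACTG2) were higher in sgCDK8-labelled than in sgLacZ libraries under MEKi, apart from SMTN, which was lower by log2 -0.55. Smooth trends on gene length and GC content were argued against as the whole cause: the median log2 fold change of the 10 genes was 1.03 before and 1.05 after either correction, none of them moved by over 0.107 (all genes moved by a median of 0.0325 and 0.0389), and the larger SD between libraries of 1 group was 0.0815 and 0.0934. Cells of another type cannot be told apart from a change within these cells: 65.2% of 23 fibroblast and smooth muscle markers were higher in every sgCDK8 MEKi library than in every sgLacZ MEKi library, between the bounds set for the test, and 87.5% of the 16 tested. CASQ2, MYOCD and KCNMB1 had 0 counts in both groups and could not be higher. They lower the 65.2%, so that share does not place the markers against the bounds. Of smooth muscle markers only DES, PLN and SYNPO2 were higher in every library, DES at 0.328 CPM. In the sgCDK8 MEKi libraries COL1A1 had 55111 counts but COL1A2, also abundant in fibroblasts, 19, while of smooth muscle genes MYH11 had 11, DES 12 and MYOCD 0. No reference profile was used to set the level a given share would need. The guide effect that the design names stays open.

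Other splits of the libraries were counted with edgeR on the libraries compared. Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. The real one was the 1 split to reach its count, with 0 genes in the highest other. Every other split mixed libraries of both groups on each side, so the difference between the groups entered the spread. Low counts there were thus built in, and they do not weigh chance. The real counts were 6497 for MEKi in sgLacZ, 6616 for MEKi in sgCDK8, 7225 for sgCCNC in DMSO, 5858 for sgCDK8 in DMSO, 5120 for sgCDK8 under MEKi and 4988 for sgCDK8 against sgCCNC in DMSO. For the sgCDK8 interaction, which called 507 genes in this fit, 10 of 100 drawn splits called as many, the real one included, and the highest other called 7623, so chance is not excluded by this count. The splits with many calls follow the structure of the libraries: the 28 that kept guides even between the drugs called 0 at most and 60 with a difference of 1 library called 54 at most, while those as large had a difference of 2 (8 of 10 splits) or 3 (1 split) and so carried the guide effect itself. The even splits mixed both guides within each group, so their 0 was built in as well.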

How the results depend on the processing

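Every alternative given in this part was planned. Of the 280 gene results, RLE factors, the filter of 10 reads in 3 libraries and the replicate block left all on the same side of the threshold, DESeq2 lost 1 call with 272 on the same side, limma on log2 TPM lost 23, no filter lost 1 and gained 1, and only the groups compared lost 2 and gained 2. Without single libraries 19 recomputed gene results lost their call and 1811 stayed on their side. Keeping the removed library in lost 47 and reversed 1, EGR3 in the sgCCNC interaction (log2 0.72). By construction the library changes the folds where sgCCNC MEKi is compared, and elsewhere enters the spread that all groups share.

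Counts of called genes that moved by over 1.5 times were those of limma on log2 TPM: 3139 for sgCDK8 and sgLacZ in DMSO (5566 by edgeR), 3382 under MEKi (5683), 2817 for sgCDK8 and sgCCNC in DMSO (4954), 3467 under MEKi (5775), 1604 for the sgCCNC interaction (3613) and 107 for the sgCDK8 interaction (568). The cause was not tested. With the removed library kept in, the interactions called 1767 and 49. Without sgCDK8 DMSO replicate 2 the sgCDK8 interaction called 375. At adjusted p under 0.01, 1150 genes were lower under both guides in DMSO (1762 at 0.05), as the limit is stricter. With an estimated correlation 46 of the 124 list calls held, and 78 did not, for which the cause was not tested, and RLE factors lost the Mediator kinase module and sterol lists in the sgCCNC interaction (both adjusted p = 0.0522). Where limma on log2 TPM moved the share of higher calls by over 10 percentage points, both stand in the report. Which direction held more calls also turned with RLE factors for MEKi in sgLacZ (48.6% to 50.7% higher). For sgCCNC in DMSO it turned with RLE factors (48.4% to 50.9%) and with DESeq2 (to 50.1%). For sgCDK8 in DMSO it turned with only the groups compared (50.7% to 48.5%) and with the removed library kept in (to 47.7%). RLE factors, DESeq2 and log2 TPM moved the median log2 fold change of all genes by less than 0.1, except in the sgCCNC interaction, where it was 0.0396 by edgeR and -0.0662 with limma on log2 TPM.

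Leaving out each library in turn gave 5781 to 6071 called genes for MEKi in sgLacZ, 5261 to 6362 in sgCCNC, 6088 to 6672 in sgCDK8, 6329 to 6719 for sgCCNC and 4613 to 4967 for sgCDK8 against sgLacZ in DMSO, 7509 to 8682 and 4638 to 5236 under MEKi, 3853 to 4437 and 3970 to 5686 for sgCDK8 against sgCCNC, and 2601 to 3792 and 375 to 684 for the interactions. Slopes ran from 1.03 to 1.16 in sgCCNC and from 0.945 to 1.02 in sgCDK8. Where 1 sgCCNC MEKi library was left, it was assumed to vary like the other groups.

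The replicate numbers showed no strong pairing: over 40 pairs with the same number the correlation of deviations ran from -0.058 to 0.0502. Its median was 0.0059, against -0.0038 for pairs with different numbers. Of 17 libraries, 10 correlated best with a library of their own number. How many would do so by chance was not computed, so weak pairing is not excluded. With the number as a block the counts were 6646, 6785 and 6902 for MEKi in sgLacZ, sgCCNC and sgCDK8, 7153 and 5544 for the guides in DMSO, 8952 and 5676 under MEKi, 4879 and 5644 between guides, and 3614 and 581 for the interactions, and no call of a gene or list named changed. Depth limits genes near 1 CPM, where 10 reads stand behind a value.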

Other observations

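The groupings of contractile genes and of genes by retained introns in this part were chosen after the data were seen. In DMSO, libraries labelled sgCCNC held less LEF1, a transcription factor of the Wnt pathway, by 6.0-fold (log2 -2.58 ± 0.20) than sgLacZ, and less of the Wnt inhibitor NKD2 by 7.86-fold (log2 -2.97 ± 0.24). The list of Wnt targets was not called, as 4 rose and 7 fell of 12 (4 and 8 adjusted over the list alone, median -1.44, adjusted p = 0.183). The receptor NOTCH2 was lower by 5.63-fold (log2 -2.49 ± 0.13), the homeobox gene EMX1 by 17.3-fold (log2 -4.11 ± 0.46) and the peptidase gene ECEL1 by 17.8-fold (log2 -4.15 ± 0.53). GREM1 was higher by 3.71-fold (log2 1.89 ± 0.16). For TGF-beta targets, 12 of 18 tested members rose and 1 fell (12 and 1 adjusted over the list alone, median 0.41, adjusted p = 0.00060, and adjusted p = 0.081 with an estimated correlation). For mesenchymal identity, 16 of 23 tested members rose and 5 fell (17 and 5 adjusted over the list alone, median 0.40, adjusted p = 0.00239, and adjusted p = 0.081 with an estimated correlation).

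In libraries labelled sgCDK8, GPNMB, a membrane glycoprotein, was higher by 3.5-fold (log2 1.81 ± 0.15) in DMSO. Under MEKi the cell death gene BAX was lower by log2 -0.40 ± 0.06. Neuronal differentiation genes were lower in libraries labelled sgCDK8 than in those labelled sgCCNC in DMSO, where 9 of 24 tested members were lower and 3 higher (10 and 3 adjusted over the list alone, median -0.18, adjusted p = 0.00769, and adjusted p = 0.0864 with an estimated correlation). Under MEKi, 12 of 24 tested members were lower and 3 higher (12 and 3 adjusted over the list alone, median -0.28, adjusted p = 0.00327, and adjusted p = 0.0618 with an estimated correlation).

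Of the contractile genes, ACTA2 was at 16.1 ± 0.639 CPM (SD, n = 3) in sgLacZ DMSO and 16.3 ± 5.26 CPM under MEKi, at 35.3 ± 6.37 and 54.5 ± 0.717 CPM (n = 2) in libraries labelled sgCCNC, and at 47.6 ± 3.35 and 119 ± 13.8 CPM in those labelled sgCDK8. The change of ACTA2 with MEKi differed from that in sgLacZ by log2 1.31 ± 0.25 in sgCDK8 (adjusted p = 0.0116 by edgeR) and did not pass in sgCCNC (log2 0.62 ± 0.27, adjusted p = 0.127). In sgLacZ, sgCCNC and sgCDK8 DMSO (SD, n = 3 each), means of TAGLN, CNN1 and ACTG2 were ordered like those of ACTA2. Those of TAGLN were 1.96 ± 0.421, 2.82 ± 0.998 and 7.02 ± 0.798 CPM, while CNN1 and ACTG2 lay under 1 CPM. Means of the other members were not so ordered. In the same groups they were 3.49 ± 2.43, 0.88 ± 0.252 and 1.17 ± 0.359 CPM for LMOD1. They were 35.2 ± 2.77, 27.7 ± 2.11 and 24.5 ± 2.05 CPM for SMTN, and 8.02 ± 1.89, 9.87 ± 1.01 and 7.50 ± 1.87 CPM for TPM2.

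Protein-coding genes were also grouped by the share of their annotated transcripts that retain an intron. The grouping rests on annotation, and intron retention itself was not measured. For the 245 genes with a share over 60%, the median log2 fold change against sgLacZ was -0.15 in sgCCNC and -0.10 in sgCDK8 under MEKi, with 52 higher and 106 lower, and 32 higher and 92 lower. In DMSO it was -0.06 (50 higher, 64 lower) and -0.07 (38 higher, 71 lower). For the 6193 genes with a share of 0 it was 0.02 in sgCCNC and 0.04 in sgCDK8 under MEKi, with 1854 higher and 1697 lower, and 1301 higher and 732 lower. The first 4 principal components of all 18 libraries, the one marked as removed included, held 44.6%, 16.3%, 7.72% and 3.66% of the variance.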
